A study of Homo sapiens with 4 samples.

How the data were processed

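Total RNA from AGS cells, a human gastric adenocarcinoma line, was measured on 1-colour Agilent expression arrays, with 1 array per sample. Per the labels, RNA was extracted with a column kit, amplified and labelled with the dye Cy3. The 4 samples were grouped by the genotype given in the labels into 2 control samples and 2 CLDN6 knockdown samples. What the control cells received and which reagent lowered CLDN6 are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

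The deposited scanner files hold the intensity of each spot, linear and corrected for background within the array by Agilent Feature Extraction, with no scaling between arrays. Version 11.5.1.1 of that software is named per the file headers, and version 12.6 per the submitters' processing notes. The spot flags used here (well above background, saturated, outlier) were set by the same software, per the file headers. A deposited table of the whole series holds the authors' log2 values for each probe and sample. Over 11791 probes with a log2 signal above 6, differences between its columns matched log2 scanner signals scaled to the 75th percentile, with the same direction. The match was exact to a standard deviation (SD) of 2.63e-07 to 4.55e-07 only if the columns of the knockdown replicates were interchanged. Under their own labels those columns differed from the scanner files by an SD of 0.143. The scale of the deposited table is therefore log2 and its direction that of the scanner files, while the value on which each probe was centred stays unknown. The column medians were -0.32 and -0.24 for control replicates 1 and 2, and -0.32 and -0.24 for knockdown replicates 1 and 2. The interchange touches no comparison between the groups, and replicate numbers here are those of the scanner files.

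Each array had 62976 spots, of which 4259 were control spots and were left out. Outlier spots, 362 to 394 per array, were also left out, and no spot was saturated. Spots of one probe were averaged as log2 processed signal, giving 42405 probes, and each array's 75th percentile was subtracted. Before scaling, that percentile was 105.5 and 114.6 in the controls and 95.6 and 109.3 in the knockdown samples. Between 18804 and 19351 probes per array were well above background. The number of arrays limits the precision.

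Probes were named through their RefSeq accessions, without versions, and a table of human RefSeq genes on assembly GRCh38.p14. This named 27241 probes with 20249 symbols, and the other 15164 kept the name in the files. The array design refers to hg19, so no coordinates are given. A gene was represented by its probe with the highest mean over all 4 arrays, and was tested if that probe was well above background on both arrays of at least 1 group. This left 15258 genes or unnamed features, of which 11856 had a symbol. Among 2842 genes with several tested probes, 21 had probes that passed in opposite directions. Probes cannot always tell near-identical genes apart, so values of KRT6A, KRT6B and KRT6C, of PMCH and PMCHL1, of SLC2A3 and SLC2A14 and of members of the histone clusters are uncertain as to the gene.

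Groups were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes without an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all tested features and a threshold of 0.05. There were 2 residual degrees of freedom and 4.63 in total after borrowing across genes. Standard errors (SE) are those of the moderated fit. Where a gene was not well above background on any array of a group, only a bound is given as its fold, and a log2 difference is named as fitted. It is the mean of the bright group over the mean, per array, of the higher of the gene's own signal and the lowest signal among probes well above background. A bound holds only for the software's background correction. That lowest signal belongs to the dimmest such probe and is no detection limit. Genes not well above background can exceed it, as KRT6B did in the controls. The words "at least" below refer to this bound only. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 33 lists. Calls were compared with an estimated correlation, with fry and with camera on ranks. Camera asks whether a list's members change more than other genes, and fry whether they change at all. With an estimated correlation, unlike with the preset value, camera takes its p on the 2 residual degrees of freedom. The share of 10000 random lists, matched on mean signal, with a lower or higher median was also taken.

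The fit and camera were tested on simulated data drawn from the means and spread of 19007 probes, with 67 probes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The fit recovered 83.3% of probes changed 4-fold, 40.3% of those changed 2-fold and 4.48% of those changed 1.5-fold, with 5 false calls among 90. Camera recovered all 5 shifted lists and called 0 of 15 unshifted ones, and with an estimated correlation it recovered 3 of 5. Probes were drawn independently and lists at random, so false calls for lists whose genes vary together were not assessed. A far smaller share of probes was changed than the 27.5% of features called in the data, so the recovery rates need not carry over.

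Except where stated below, the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. CLDN6, YAP1 and SNAI1 were always named. Among genes with a symbol that passed and whose groups did not overlap, the rule then took the 10 largest increases and 10 largest decreases well above background on all arrays. It further took up to 4 genes in each direction that were well above background in only 1 group, and up to 4 members of each list with the smallest p. Not every gene that the rule took is printed. The lists covered tight junctions, adherens junctions and desmosomes, the Hippo pathway, YAP/TAZ targets, epithelial-mesenchymal transition (EMT), epithelial markers, integrins and matrix proteases, G1/S, G2/M, p53 targets, apoptosis regulators, the interferon response, NF-kB and cytokines, and hypoxia and glycolysis. They further covered the unfolded protein response, ATF4 targets, cholesterol synthesis, fatty acid synthesis, heat shock, NRF2 targets, MAPK output, Wnt, Notch and TGF-beta targets, MYC and ribosome biogenesis, oxidative phosphorylation, ribosomal proteins, replication-dependent histones, gastric and intestinal epithelium, and fibroblast, leukocyte and endothelial markers.

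Alternatives were quantile normalization, scaling to the median of probes well above background on all arrays, normexp background correction with an offset of 50, the deposited log2 table, no filter or a stricter filter on dim probes, the mean of a gene's probes, eBayes with a trend or robust, the replicate number as a block, and leaving out each array. The normexp alternative was planned on mean spot signals and was run on median spot signals, which the files hold. All 4 arrays lay on 1 slide and were read in 1 scan, so neither could be used as a block. The slide row as a block was added after the data were seen.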

Results

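Gene expression was measured in AGS cells, an epithelial line from a human gastric adenocarcinoma, with and without knockdown of CLDN6, which encodes claudin-6, a membrane protein of tight junctions. The stated purpose was to find the molecular pathways that knockdown of CLDN6 affects. Each group had 2 samples, with 1 array each, and all values below are log2 signals relative to the array's 75th percentile or differences between them. Over 17850 probes well above background on all arrays, the replicates correlated at 0.997 across probes in the controls and at 0.997 in the knockdown samples. Probes are not independent replicates, and these correlations describe the arrays only. The SD of the difference between replicates was 0.205 in the controls and 0.203 in the knockdown samples, against 0.419 for the difference between the group means. The former are differences between single arrays and the latter between means of 2 arrays, which noise moves less, so these SDs are not on one scale.

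The targeted gene was measured first. CLDN6 stood at 3.15 and 3.32 in control replicates 1 and 2, and at -4.16 and -3.75 in knockdown replicates 1 and 2, where its only probe was not well above background. CLDN6 was therefore at least 103.5-fold lower in the knockdown samples (limma adjusted p = 0.000673). Its fitted log2 difference, which gives no fold where a group is not well above background, was -4.11 with normexp background correction and -7.19 without it. Without a filter on dim probes, which raised the number of tested features to 34390, CLDN6 did not pass, with an adjusted p of 0.0525.

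**Figure D1:**
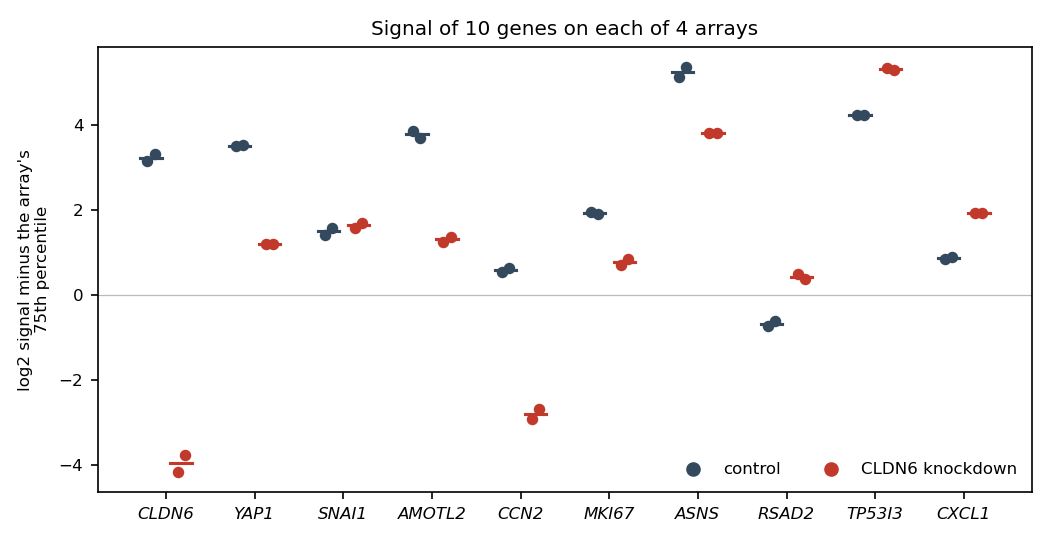
Log2 signal minus the array's 75th percentile for 10 genes, with 1 point per array and a bar at each group's mean (n = 2 per group). CLDN6 lay at 3.15 and 3.32 in the controls and at -4.16 and -3.75 in the knockdown samples, and the groups of SNAI1 differed by 0.14 with an adjusted p of 0.338.

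Knockdown of CLDN6 went with lower YAP1, the transcriptional coactivator restrained by the Hippo kinases, and with higher and lower levels of many other genes. Of 15258 features tested, 4193 changed, with 2163 higher and 2030 lower in the knockdown samples. At least 2-fold changes numbered 610, of which 217 rose and 393 fell. Without any test, 651 features were at least 2-fold apart with groups that did not overlap, 237 up and 414 down. Groups did not overlap in 68.9% of all features, against 33.3% by chance with 2 samples against 2. Leaving out 1 array lowered the count of changed features to 1990 without control replicate 1, 1906 without control replicate 2, 1668 without knockdown replicate 1 and 1861 without knockdown replicate 2, and more fell than rose in each case. Without the filter on dim probes, limma called 1 feature, NPPB, while 5929 of 34390 had an unadjusted p under 0.05. With normexp correction, 179 features changed at least 2-fold.

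Among genes well above background on all arrays, the largest increases were of TCN1, a vitamin B12 binding protein, which rose by 3.91 ± 0.09 (log2, SE, n = 2 per group; adjusted p = 0.000673), and PMCH, the precursor of melanin-concentrating hormone, which rose by 3.07 ± 0.07 (adjusted p = 0.000673). The next were MIA (5.03-fold higher), the mucin MUC13 (4.69-fold), RGS5 (4.502-fold), SMPX (4.37-fold), the aryl hydrocarbon receptor target CYP1A1 (4.21-fold), the lipid transporter ABCA12 (3.98-fold), S1PR4 (3.83-fold) and SERPINA3 (3.80-fold, and by 2.84 in log2 with its other probe). Keratin 6B, KRT6B, was not well above background in the controls and was 20.55-fold higher in the knockdown samples as fitted. For KRT6B the bound equals this fitted fold, since its own control signal set it, so it is no lower limit. Also not well above background in the controls, PMCHL1 was at least 11.1-fold higher, the epithelial transcription factor EHF at least 3.87-fold and CELA2A at least 3.55-fold. The adjusted p of these 4 genes lay between 0.000528 and 0.00808. PMCH and PMCHL1 are near-identical in part, as are the KRT6 genes, and their values are uncertain as to the gene.

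The largest decrease among genes well above background on all arrays was that of SERINC3, which fell by 4.05 ± 0.09 (log2, SE, n = 2 per group; adjusted p = 0.000673), and its other tested probe fell by 4.07. STRADB was 8.12-fold lower (log2 difference -2.33 with its other probe), FMC1 7.74-fold, SCARNA9 7.14-fold and TMEM179B 6.58-fold. The keratins KRT17 and KRT14, which mark basal epithelium, were 7.54-fold and 5.65-fold lower. AMOTL2, an angiomotin that binds YAP1, was 5.54-fold lower, and the glucose transporter SLC2A14, whose sequence is close to that of SLC2A3, was 5.51-fold lower. NPPB, the precursor of a natriuretic peptide, was not well above background in the knockdown samples and was at least 45.5-fold lower (adjusted p = 0.000236). MAB21L4 was at least 7.56-fold lower and ACP3 at least 4.78-fold lower. With normexp correction, 35 of 143 named genes that passed, CLDN6 aside, had a fold more than 1.5 times smaller, and 0 changed direction. Of the increases above, the fitted log2 difference was then 1.86 for TCN1, 2.07 for PMCH, 1.16 for MUC13, 1.33 for RGS5, 1.42 for CYP1A1, 0.96 for ABCA12, 1.16 for S1PR4, 0.86 for SERPINA3, 2.09 for KRT6B, 1.33 for PMCHL1, 0.69 for EHF and 0.55 for CELA2A. Of the decreases it was -2.07 for STRADB, -1.30 for FMC1, -2.00 for KRT17, -2.02 for TMEM179B, -1.84 for KRT14, -2.90 for NPPB, -1.14 for MAB21L4 and -0.61 for ACP3.

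**Figure D2:**
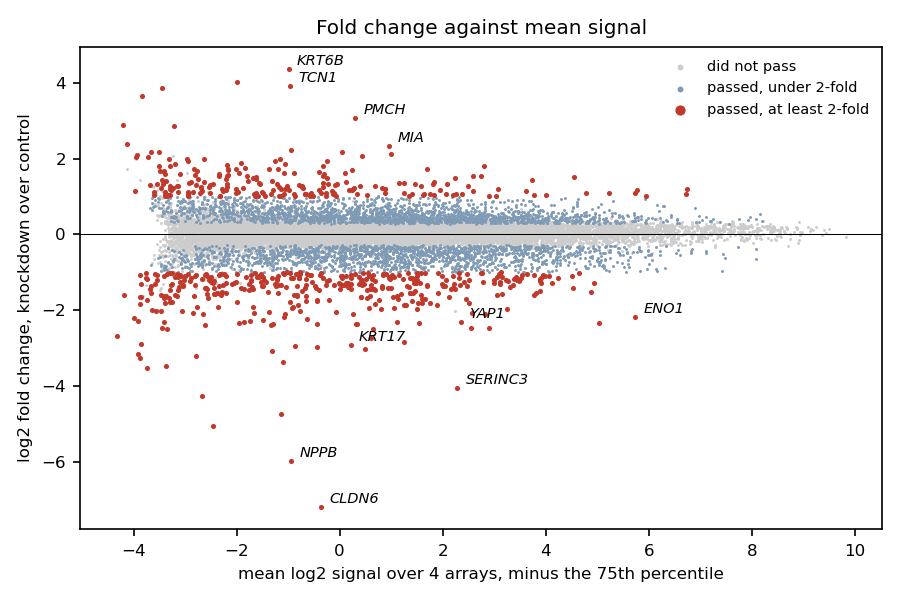
Log2 fold change of knockdown over control against the mean log2 signal over 4 arrays, with 1 point per tested feature (15258), coloured by whether it passed an adjusted p of 0.05 and by size. The 393 features that fell at least 2-fold outnumbered the 217 that rose, and CLDN6 lay lowest; fold changes of features not well above background in a group are fitted values, not bounds.

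YAP1 fell by 2.31 ± 0.07 (log2, SE, n = 2 per group; adjusted p = 0.0014), 4.96-fold. In the published 22-gene signature of YAP and TAZ activity, 13 of 14 measured members fell and 1 rose, adjusted over all genes and adjusted over the list alone (camera adjusted p = 5.42e-09; adjusted p = 0.484 with an estimated correlation). CCN2, a secreted matrix protein, fell by 3.37 and was well above background on 1 of the 2 knockdown arrays, as was ANKRD1, which fell by 4.72 and was named after its value was seen. CCN1, of the same family, was 3.94-fold lower and the phosphatase PTPN14 3.03-fold lower. The member that rose was GADD45A, a DNA damage response gene also among the p53 targets, by 0.39 ± 0.08, named after its value was seen. Of the Hippo pathway's own components, 11 of 28 fell and 2 rose, and 12 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.00729; adjusted p = 0.484 with an estimated correlation). Those with the smallest p were YAP1, AMOTL2, PTPN14 and WWC2, the last at least 3.12-fold lower. AMOTL2, PTPN14 and LATS2 belong to both lists. LATS2, named after its value was seen, fell by 0.82 ± 0.11. The median of the Hippo list was -0.12. With normexp correction the fitted log2 difference of CCN2 was -1.52 and that of WWC2 -0.44.

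Most measured members of the cell cycle lists fell. Among genes that peak in G2 and mitosis, 42 of 48 fell and 0 rose, with a median log2 change of -0.85, and 44 fell adjusted over the list alone (camera adjusted p = 1.12e-21; adjusted p = 0.484 with an estimated correlation). The proliferation marker MKI67 was 2.23-fold lower, the phosphatase CDC25C 2.34-fold, CDCA8 of the chromosomal passenger complex 2.33-fold and the centromere chaperone HJURP 2.20-fold. Among genes of G1/S and DNA replication, 37 of 43 fell and 0 rose, with a median of -0.59, and 40 fell adjusted over the list alone (camera adjusted p = 3.02e-17; adjusted p = 0.484 with an estimated correlation). DTL was 3.86-fold lower and the transcription factor E2F1 2.45-fold. Of the replication-dependent histones, 24 of 32 fell and 0 rose, with a median of -0.70, and 26 fell adjusted over the list alone (camera adjusted p = 1.20e-11; adjusted p = 0.520 with an estimated correlation). H2BC11 was 2.10-fold lower, H3C2 2.01-fold, H3C10 2.01-fold and H2BC3 1.79-fold.

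The lists of ATF4 targets and of cholesterol synthesis passed, with more members that fell than rose. Of the targets of ATF4, the transcription factor of the integrated stress response, 20 of 30 fell and 2 rose, with a median of -0.50, and 20 fell and 3 rose adjusted over the list alone (camera adjusted p = 1.14e-07; adjusted p = 0.484 with an estimated correlation). CHAC1, which degrades glutathione, was 4.23-fold lower, CTH 2.70-fold, asparagine synthetase ASNS 2.68-fold and the pseudokinase TRIB3 2.42-fold. Of the genes of cholesterol synthesis, 11 of 24 fell and 1 rose, and 14 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.24e-05; adjusted p = 0.484 with an estimated correlation). INSIG1 was 3.21-fold lower and ACAT2 1.61-fold. In the list of hypoxia and glycolysis, 8 of 31 fell and 4 rose, 9 and 7 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.172). It held the glucose transporter SLC2A3, 5.18-fold lower, and the glycolytic enzyme ENO1, 4.56-fold lower, with PFKFB3 1.70-fold and BNIP3L 1.98-fold lower. The other tested probes of SLC2A3, PFKFB3 and BNIP3L differed by -3.31, -0.38 and -0.20 (log2). With normexp correction SLC2A3 differed by -1.67.

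The lists of the interferon response, NF-kB targets and p53 targets passed, with more members that rose than fell. Of the interferon response list, 23 of 46 rose and 1 fell, with a median of 0.40, and 25 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.88e-05; adjusted p = 0.520 with an estimated correlation). The chemokine CXCL11 was 2.30-fold higher, though well above background on 1 of the 2 control arrays, and the antiviral protein RSAD2 2.14-fold, the peptide transporter TAP1 1.94-fold and IFI44 1.78-fold higher. Of NF-kB targets and cytokines, 13 of 21 rose and 1 fell, adjusted over all genes and adjusted over the list alone (camera adjusted p = 0.00729; adjusted p = 0.520 with an estimated correlation). BIRC3, an inhibitor of apoptosis, was 2.12-fold higher, and the chemokines CXCL1 and CXCL3 2.09-fold and 1.59-fold higher, the call of CXCL3 being lost in 3 of 15 alternatives. The member that fell was the cyclooxygenase PTGS2, 2.38-fold lower. With normexp correction the log2 difference of CXCL11 was 0.40 and that of PTGS2 -0.37. Of p53 targets, 16 of 31 rose and 2 fell, 19 and 2 adjusted over the list alone (camera adjusted p = 0.000918; adjusted p = 0.484 with an estimated correlation). TP53I3 was 2.11-fold higher, FDXR 1.92-fold, the death receptor TNFRSF10B 1.68-fold and PMAIP1, a BH3-only protein, 1.67-fold. Of apoptosis regulators, 7 of 30 rose and 3 fell, 8 and 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.179). BIK was 1.75-fold higher and CFLAR 1.498-fold lower, with a log2 difference of only -0.11 for another of its probes and its call lost in 2 of 15 alternatives.

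**Figure D3:**
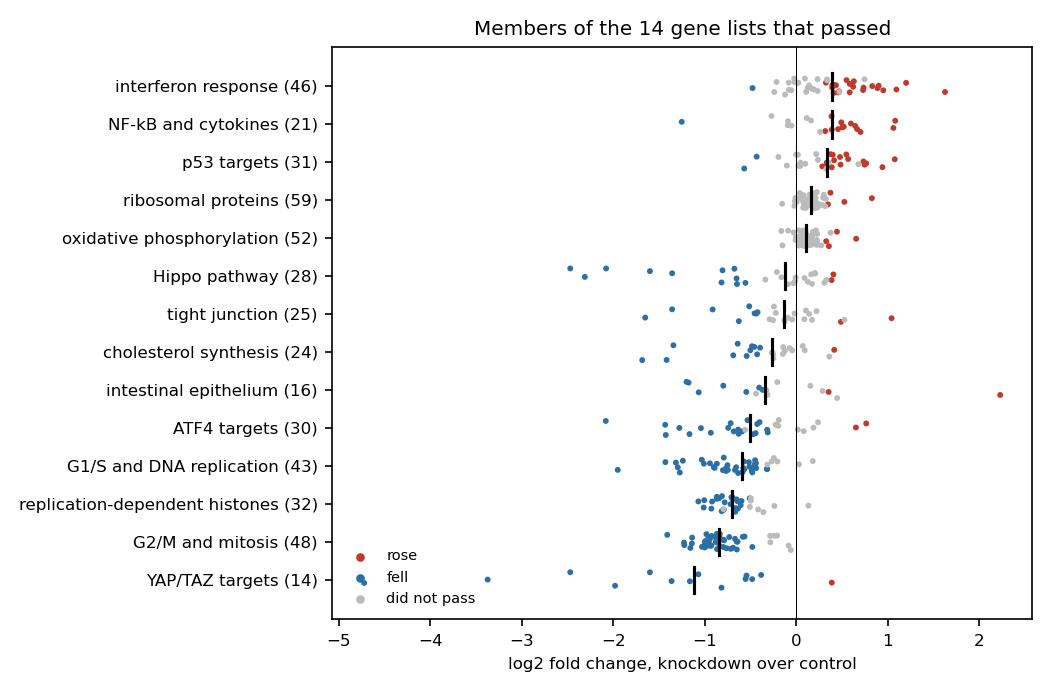
Log2 fold change of knockdown over control for each measured member of the 14 lists that passed camera at a preset correlation of 0.01, with 1 point per gene, a bar at the list's median and the number of measured members in brackets. Medians ran from -1.11 for YAP/TAZ targets to 0.40 for the interferon response; no list passed with an estimated correlation.

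Junction genes other than CLDN6 moved both ways. In the tight junction list, 8 of 25 fell and 2 rose, adjusted over all genes and adjusted over the list alone (camera adjusted p = 0.0359; adjusted p = 0.563 with an estimated correlation). The virus receptor CXADR was 3.14-fold lower, the polarity protein PARD6B 2.56-fold and cingulin, CGN, 1.54-fold, while claudin-2, CLDN2, was 2.06-fold higher. The list did not pass without control replicate 2 or without knockdown replicate 2, and neither by fry nor on ranks. Of adherens junction and desmosome genes, 5 of 20 fell and 1 rose, 6 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.186). DSC2 was 1.87-fold, PPL 1.77-fold and PKP2 1.54-fold lower, and NECTIN4 1.497-fold higher. The call of PKP2 was lost in 5 of 15 alternatives and that of NECTIN4 in 4.

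SNAI1, a transcription factor that represses epithelial genes, was higher by 0.14 ± 0.10 (log2, SE, n = 2 per group) and did not pass (adjusted p = 0.338). The EMT list did not pass (camera adjusted p = 0.963), with 4 of 11 members higher and 4 lower, 5 and 4 adjusted over the list alone. S100A4 was 1.91-fold, ZEB1 1.54-fold and vimentin, VIM, 1.43-fold higher, and SNAI3 2.91-fold lower. The call of VIM was lost in 5 of 15 alternatives and that of ZEB1 in 3, and SNAI3 differed by -0.42 (log2) with normexp correction. Of epithelial markers, 2 of 29 rose and 7 fell, 4 and 9 adjusted over the list alone (camera adjusted p = 0.317). Its members included EHF, named above, LAD1, 1.90-fold higher, OVOL1, 2.29-fold lower, and S100A14, 1.77-fold lower. Integrins and matrix proteases held 9 of 22 that rose and 3 that fell, 10 and 5 adjusted over the list alone, and did not pass (camera adjusted p = 0.166). The protease MMP7 was 3.30-fold higher and the hyaluronan receptor CD44 1.86-fold, ITGB8 2.92-fold higher with 1 of 2 control arrays well above background, and the laminin chain LAMC1 2.65-fold lower. With normexp correction the log2 difference of MMP7 was 0.78 and that of ITGB8 0.46. Of intestinal markers, 7 of 16 fell and 2 rose, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0337; adjusted p = 0.484 with an estimated correlation). The intestinal transcription factor CDX2 was 2.26-fold lower, REG4 2.29-fold and the cadherin CDH17 1.74-fold, while MUC13 rose. The intestinal list did not pass with normexp correction, with another filter on dim probes, with an intensity trend or on ranks. Of gastric markers, 1 of 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.796): ANXA10 was at least 2.40-fold higher and SOX2 1.40-fold lower, a call that was lost in 5 of 15 alternatives, and the fitted log2 difference of ANXA10 was 0.29 with normexp correction.

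Ribosomal proteins and subunits of the respiratory chain passed with small shifts. Of ribosomal proteins, 4 of 59 rose and 0 fell, with a median of 0.16, and 1 rose adjusted over the list alone (camera adjusted p = 0.00506; adjusted p = 0.520 with an estimated correlation). Of oxidative phosphorylation genes, 4 of 52 rose and 0 fell, with a median of 0.10, and 1 rose adjusted over the list alone (camera adjusted p = 0.0226; adjusted p = 0.681 with an estimated correlation). The median over all features was 0.06. Among random lists matched on mean signal, 22.3% had a higher median than the oxidative phosphorylation list. For the other 13 lists that passed, at most 1.07% had a median further in the direction of the change. With quantile normalization neither list passed. The oxidative phosphorylation list also did not pass without control replicate 1 or without knockdown replicate 1, with normexp correction or by fry.

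By fry, 5 lists that did not pass camera passed beside the fibroblast list: adherens junctions and desmosomes (adjusted p = 0.0193) and hypoxia and glycolysis (0.0143) with direction down, and integrins and matrix proteases (0.0427), apoptosis regulators (0.0337) and the unfolded protein response (0.0484) with direction up. Since fry does not compare a list with other features, of which 27.5% were called, these passes do not set the lists apart. The remaining lists on signalling and metabolism did not pass camera. The MAPK output list had 8 of 30 higher and 8 lower, 9 and 8 adjusted over the list alone (adjusted p = 0.603), with PHLDA1 2.54-fold, EGR2 1.69-fold and DUSP6 1.54-fold higher and HBEGF 1.72-fold lower. Wnt targets had 6 of 18 higher and 3 lower, 6 and 4 adjusted over the list alone (adjusted p = 0.603), with TCF7 2.26-fold (log2 difference -0.62 with its other probe) and DKK1 1.97-fold lower and NKD1 2.04-fold higher. Notch targets had 3 of 13 higher and 4 lower, 3 and 5 adjusted over the list alone (adjusted p = 0.192), with HEY1 at least 1.72-fold higher and MFNG 1.69-fold lower, a call lost in 2 of 15 alternatives; with normexp correction their fitted log2 differences were 0.28 and -0.16. TGF-beta targets had 4 of 22 higher and 5 lower, 4 and 7 adjusted over the list alone (adjusted p = 0.270), with the cell cycle inhibitors CDKN2B 3.05-fold higher (0.82 in log2 with normexp correction) and CDKN1C 2.27-fold lower. The unfolded protein response had 3 of 23 higher and 4 lower, 4 and 4 adjusted over the list alone (adjusted p = 0.239), with DNAJB9 2.49-fold higher and XBP1 1.86-fold lower. Fatty acid synthesis had 2 of 17 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.603), heat shock 2 of 22 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.971), and NRF2 targets 4 of 26 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.810). Examples were ACLY, 1.47-fold lower with its call lost in 4 of 15 alternatives, HSPB1, 2.12-fold higher, and AKR1B10, 2.41-fold lower. MYC targets and ribosome biogenesis had 4 of 37 higher and 2 lower, 2 and 2 adjusted over the list alone (adjusted p = 0.2499), with DDX18 1.66-fold and MAX 1.64-fold lower, the latter with a log2 difference of only -0.09 for another of its probes.

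Markers of cells not expected in an epithelial line were mostly not detected. Of 18 fibroblast markers on the array, 4 were well above background on both arrays of each group, of 19 leukocyte markers 6 in each group, and of 14 endothelial markers 1 in each group. No list of these passed camera, with adjusted p values of 0.270, 0.389 and 0.192. By fry, the fibroblast list passed with direction down (adjusted p = 0.01004). Among the tested fibroblast markers PDGFRA was 3.88-fold and COL1A1 1.46-fold lower and C1R 1.71-fold higher, so that 1 of 4 rose and 2 fell, also adjusted over the list alone. Among 7 tested leukocyte markers 1 rose and 1 fell, also adjusted over the list alone, with CD68 1.68-fold higher and CD14 at least 1.22-fold lower, a call that was lost in 9 of 14 alternatives. The tested endothelial marker, ESAM, was 1.53-fold lower, adjusted over all genes and adjusted over the list alone. The calls of ESAM and of COL1A1 were each lost in 5 of 15 alternatives, and that of CD68 in 2.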

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

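The slide row as a block was chosen after the data were seen, and all other alternatives were planned. No named gene or list that had passed changed direction under any alternative. The count of 4193 changed features fell to 1 without a filter on dim probes, where the 610 with at least 2-fold changes also fell to 1, the 651 separated features rose to 1362 with 34390 features tested, and CLDN6 kept its fitted log2 difference of -7.19 with an adjusted p of 0.0525. Over the other settings the adjusted p of CLDN6 lay between 2.65e-11 and 0.0233. With normexp, which adds an offset and so shrinks the changes of dim genes, 179 features changed at least 2-fold and 179 were separated at least 2-fold. The slide row as a block gave 2450 changed features, 2359 of them among the 4193. Leaving out 1 array gave between 1668 and 1990 changed features, of which 1568 to 1807 were among the 4193; the group left with a lone array was assumed to vary like the other. With an estimated inter-gene correlation 0 of 33 lists passed, against 14 with the preset value, 18 by fry and 12 on ranks. That setting takes p on the 2 residual degrees of freedom, so a lost call need not come from correlation between genes. Calls were lost with estimated correlations below the preset 0.01, as for the Hippo pathway (-0.0065) and p53 targets (-0.031). They were also lost with higher ones, as for YAP/TAZ targets (0.336) and G2/M genes (0.307). The replicate number as a block, which is also the slide column, gave 3461 changed features, 619 at least 2-fold and 14 lists. Deviations of same-numbered samples correlated at -0.02 across probes. Among 143 named genes other than CLDN6 that passed, 113 passed with any 1 array left out and 30 did not in at least 1 case. Under 4 other scalings or sources of values, the median over all features lay between 0.04 and 0.06 and the share of rises between 50.5% and 53.7%, against 51.6%. The share of rises turned below 50% with each array left out (38.2% to 47.2%), with the slide row as a block (46.4%) and with the replicate number as a block (49.0%). Neither the slide nor the scan could be used as a block, and a plain t-test was not run, since no source used here shows that the authors used one. The count of separated features does not depend on the variance prior or a block. CLDN6 gave no value under the filter of all 4 arrays, since it was not well above background in the knockdown samples. The causes of the other shifts were not tested.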

Other observations

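Gene families and classes of RNA, 21 in all, were chosen after the data were seen and tested with camera. Kinesins, motor proteins of which many act in mitosis, and CENP proteins of the centromere passed with direction down, with 14 of 26 lower and 2 higher, and 14 of 19 lower and 0 higher (adjusted p = 1.11e-05 and 2.01e-07). Cationic and neutral amino acid transporters of the SLC7A family and glucose transporters of the SLC2A family passed with direction down, with 4 of 7 and 4 of 9 lower and 0 higher (adjusted p = 0.00412 and 0.00802). These 4 families share members with lists reported above, so they are not separate evidence. KIF11, KIF23, CENPE and CENPF are in the G2/M list, SLC7A1 and SLC7A5 among ATF4 targets and SLC2A3 in the hypoxia list. SLC2A3 and SLC2A14, which probes may not tell apart, both count as lower. Metallothioneins, which bind zinc and copper, and HLA genes passed with direction up, with 5 of 8 and 5 of 9 higher and 0 lower (adjusted p = 0.00802 and 0.0131). Zinc finger genes of the ZNF series passed with direction up, with 77 of 350 higher and 16 lower (adjusted p = 0.00373). All 7 have an adjusted p of 0.674 with an estimated correlation, and the signs of their medians held under the 5 scalings. Keratins moved both ways, with 5 of 18 higher and 6 lower. Those changed at least 2-fold were KRT17, KRT14 and KRT80, which fell, and KRT23, KRT6A, KRT6C and KRT6B, which rose.

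For the patterns below, the tests of scaling and of silencing were chosen after the results they concern had been seen. The interferon genes tested for a response to foreign RNA belong to a list whose median had been seen.

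The fall of YAP1 and of YAP/TAZ targets was weighed against a faulty probe, scaling, and silencing of other transcripts by the knockdown reagent. Scaling is argued against, since a constant per array moves all features alike and cannot part the list from them, and under quantile normalization and normexp, which can, its median still lay below that of all features (differences -1.16 and -0.69, log2). A faulty YAP1 probe bears only on the YAP1 value, which stays open, as 0 other YAP1 probes were well above background; the targets have probes of their own. Silencing of unrelated transcripts stays open: outside CLDN6 and the YAP/TAZ list, all 27 genes above the 75th percentile in the controls and changed at least 4-fold fell, which is 100% (exact 95% interval 87.2 to 100), YAP1 among them, and so did the 26 without YAP1. That test, as written, selects genes on the controls and so favours falls. Checks added to it left out YAP1. Of 35 genes bright in either group, 74.3% fell (56.7 to 87.5). Of 21 bright by the mean of all arrays, 76.2% fell (52.8 to 91.8). Of 16 bright in the knockdown samples, a choice that in turn favours rises, 43.8% fell (19.8 to 70.1). Among all 610 features that changed at least 2-fold, 393 fell. The intervals treat genes as independent. Direction alone cannot tell silencing by the reagent from other origins of a fall. Whether a reagent acting on other transcripts accounts for part of the pattern was not decided, and no sequence was at hand to test it.

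The fall of cell cycle genes was weighed against intensity-dependent bias, position on the slide and p53 activation. Intensity-dependent bias is argued against, as 0% of 10000 random lists matched on mean signal had a median as low as that of the G1/S or of the G2/M list. An effect of the slide row or column alone is argued against. Knockdown and control arrays of the same row or column gave 4 comparisons. The median of 91 cycle genes was -0.67 or lower in each. Controls lay at row 1, column 1 and row 2, column 2, and knockdown samples at row 2, column 1 and row 1, column 2. A position effect along these diagonals cannot be told from the group. Activation of p53 stays open as a biological candidate explanation: CDKN1A rose by 0.49 ± 0.09 (adjusted p = 0.0222), short of the 0.5 set in advance as needed and above the 0.25 set as too low, and MDM2 did not pass, at 0.10 ± 0.08 (adjusted p = 0.391). Loss of CLDN6 or of YAP1 as the origin was not tested.

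The rise of interferon-stimulated genes was weighed against intensity-dependent bias, leukocytes in the culture and a response to foreign RNA. Intensity-dependent bias is argued against, as 0% of matched random lists had a higher median. Leukocytes in the culture were not decided by the test set in advance, since 2 of 7 markers, TYROBP and FCER1G, were well above background on both knockdown arrays. PTPRC, CD3E, CD2, HBB and CD14 were not. FCER1G was well above background on both control arrays too. CD14 was at least 1.22-fold lower (adjusted p = 0.0322). TYROBP and FCER1G did not pass, at 0.24 ± 0.12 (adjusted p = 0.197) and 0.02 ± 0.09 (adjusted p = 0.910). A response to foreign RNA in the knockdown cells was not decided either. The median of 12 core genes was 0.47, and 8 of the 12 rose. ISG15 (0.34), OAS1 (0.19), OAS3 (-0.12) and MX1 (-0.24) did not pass. The 12 genes are part of the pattern and could rise in any interferon response, so they cannot point to foreign RNA. What the control cells received is not given in the sources used here, so such a response and an effect of CLDN6 loss cannot be told apart by design; probes of IFNL1, IFNL2 and IFNE were well above background on all arrays of both groups, and that of IFNB1 on none.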
